A study of Mus musculus with 8 samples.

How the data were processed

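Single cells from mouse bone marrow were sorted, captured on a C1 microfluidic system and turned into cDNA with SMARTer chemistry and Nextera XT libraries, and wells with 0 cells, more than 1 cell or shrunken cells were excluded by microscopy, per the labels. No doublet caller was run. The deposited table held read counts of 23420 genes in 611 cells as whole numbers, without molecular identifiers. The authors named Cufflinks 2.1.1, Seurat 4, featureCounts and genome build mm10; which of these made the counts, the aligner, the annotation and the handling of duplicate reads are not given in the sources used here. Cells were assigned to 8 libraries, 1 per group, by the library name that starts each column, and the deposited cell sheet gave the 2 runs, labelled rep1 and rep2, of GFP-low cells (19 and 61 cells) and of CD41+ cells (22 and 74 cells), counted as 1 sample each; whether they come from separate animals is not stated. Library and group cannot be told apart. The sample label gives 2 months of doxycycline for the GFP libraries and the protocol 2.5 months. The table held no mitochondrially encoded gene, so the share of mitochondrial reads could not be used on cells.

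Gene lists, the naming rule, the comparisons and most alternatives were fixed before the data were examined. Each cell was thinned at random without replacement to 50000 reads, with a fixed seed, and reads were summed per library. The rule asked for the largest depth that keeps at least 90% of the cells of every library; no depth met it, and the lowest was used, which kept 88.8% of GFP-low cells and 588 of all 611 cells. The 23 shallower cells were left out. CPM (reads of a gene per 1000000 reads) were taken from the sums, log2 fold changes used a pseudocount of 1 CPM, and genes counted as expressed at 10 CPM or more in at least 1 library of a comparison. At 1 library per group no test between groups was made and cells were not used as replicates. The order of the 5 ages was tested by exact permutation of libraries. Intervals were exact Poisson and exact binomial (Clopper-Pearson), and a gene with no read was set to a floor of 3 counts summed over the library. Folds against this floor use the measured CPM of the other library and are not exact lower limits. Setting list members with no read to that floor changed none of 69 list medians, 24 of which had such members. The reads of the 100 most abundant genes rose with the total of a cell with a log-log slope of 0.651 at 10 weeks and 0.925 at 2 years, so abundant genes were not proportional to depth in these counts.

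Named genes had to reach 50 CPM and 30% of thinned cells at the higher end and differ at least 2-fold with and without the cell holding most reads of the gene. In the ageing series they also had to move strictly one way across the 5 ages, and in the other comparisons the share of cells had to differ by at least 20 percentage points the same way. The 12 highest and 12 lowest log2 fold changes were named, without predicted genes, pseudogenes and spikes, together with Pbx1, the genes of the sorting gate and the members of each list with the largest and smallest fold change. Other list members given as examples, Flt3 in the ageing series and the 44 genes nearly absent at 10 weeks were chosen after their values were seen. The 28 lists were written from general knowledge, with 542 entries apart from ribosomal proteins, which were taken by name pattern (80 genes); 20 entries had no gene in the table and 5 were found under an older symbol. Coordinates came from a RefSeq table of GRCm38.

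The fold calculation was tested on simulated data, with Poisson counts drawn from the thinned sum of 1 library of each comparison after known changes in 100, 50 and 50 genes; this leaves thinning and differences between cells untested. Median recovered against true log2 differences, after 4-fold, 2-fold and 0.25-fold changes, were 1.93 for 1.96, 0.94 for 0.96 and -1.99 for -2.04 in the ageing comparison, 1.95 for 1.96, 0.95 for 0.96 and -2.04 for -2.04 in the GFP comparison and 1.93 for 1.96, 0.92 for 0.96 and -2.01 for -2.04 in the CD41 comparison. Alternatives were unthinned sums, the mean of per-cell CPM, TMM factors of edgeR 4.0.16, median-of-ratios factors of DESeq2 1.42.0, a pseudocount of 10 CPM, no filter on low counts or 50 CPM, leaving out the top cell of each gene, cells with few genes or cells rich in G2/M reads, other ages as the young or old library, no minimum fold in the order of ages, agreement among genes of 50 CPM, and shares from at least 5 reads or from unthinned cells. Added after the data were seen were cells of at least 200000 reads without cells rich in neutrophil granule genes, cells of 400000 to 800000 reads, a second thinning, thinning to 200000 reads, each run alone, 18 against 7 months, the order of ages without the 10-week or the 2-year library, CD41+ cells against 7-month HSCs, and the agreement of the GFP and CD41 comparisons. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.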

Results

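Single haematopoietic stem cells (HSCs) and CD41+ cells from mouse bone marrow were profiled by full-length RNA sequencing on a microfluidic capture system, and 611 cells in 8 libraries were analysed. HSCs sorted as CD150+CD48-CD41-CD34- cells of the LSK (lineage-negative, Sca-1+, c-Kit+) compartment came from mice of 10 weeks (79 cells), 7 months (85 cells), 12 months (70 cells), 18 months (79 cells) and 2 years (53 cells). A further pair of libraries held GFP-high (69 cells) and GFP-low (80 cells) CD150+CD48-CD34- LSK cells of Scl-tTA:H2B-GFP mice of 14.5 months, in which doxycycline stops production of the histone-GFP label so that each division dilutes it. The last library held 96 CD150+CD48-CD41+ LSK cells of 10-week mice. Each group had 1 library. Reads assigned to genes came to 52731392 in the 10-week library, 43029063 at 7 months, 39770758 at 12 months, 38847030 at 18 months and 51899479 at 2 years. GFP-high, GFP-low and CD41+ libraries held 36251739, 39792323 and 49134344 reads. The median cell held 680923 reads and 5791 genes in the 10-week library and 1033305 reads and 5929 genes in the 2-year library, against 502619 reads and 4036 genes at 18 months. With every cell thinned to 50000 reads, median genes per cell were 2496.5 at 10 weeks, 2689.5 at 2 years, 2580.5 at 18 months and 3422 in CD41+ cells.

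Intervals below are 95% and exact, Poisson for CPM (summed reads of a gene per 1000000 reads of its library) and binomial (Clopper-Pearson) for shares of cells. The reads carried no molecular identifiers, so intervals and floors cover counting error only. Log2 fold changes are on the log2(CPM + 1) scale. The GFP-low and CD41+ libraries each held 2 parts labelled rep1 and rep2, called runs 1 and 2 here. The labels do not say whether these came from separate animals or from the same ones, so the spread between runs may be technical or between animals. The absolute log2 difference of a gene between runs had a median of 0.96 over 9618 genes in GFP-low cells and 0.74 over 9850 genes in CD41+ cells. Medians of gene lists moved less, with a median absolute difference between runs of 0.44 over 24 lists in GFP-low cells and 0.20 over 23 lists in CD41+ cells. Gene lists were therefore read before single genes, and a list is set apart below where its median lay outside the central 95% of 10000 random lists of the same size matched on expression, which describes these libraries and tests no condition. A member of a list is called higher or lower where its CPM differed by at least 1.5-fold and its share of thinned cells by at least 10 percentage points the same way.

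Pbx1, the homeobox transcription factor gene named in the title of the series (chromosome 1, 168119364 to 168432365, GRCm38), was measured in every library. Its level at 10 weeks was 299 CPM (282 to 318), and at 2 years it was 619.6 CPM (589 to 651), a log2 difference of 1.05 (0.94 to 1.16). The ages between did not lie on a line: Pbx1 stood at 652 CPM at 7 months, 513 CPM at 12 months and 250.3 CPM at 18 months, so the 2-year library was higher than the 18-month library and close to the 7-month library. GFP-low cells had the most Pbx1 of the 8 libraries, 806 CPM (777 to 836), and GFP-high cells had 452 CPM (429 to 475), a log2 difference of -0.83 (-0.93 to -0.74). CD41+ cells had 643 CPM (621 to 666), higher than young HSCs by 1.10 on the log2 scale (1.00 to 1.20). Reads of Pbx1 were found in 64.9% of thinned cells at 10 weeks (52.9 to 75.6%), 90% at 2 years (78.2 to 96.7%), 74.2% of GFP-high cells, 90.1% of GFP-low cells and 96.9% of CD41+ cells (91.1 to 99.4%). Without thinning the shares at 10 weeks and 2 years were 96.2% and 100%, and those of GFP-high and GFP-low cells 95.7% and 93.8%, so no order of these 2 is read from the shares. The runs of CD41+ cells differed in Pbx1, at 1026 CPM in run 1 and 529 CPM in run 2, both above young HSCs, so that run 1 alone gave a log2 difference of 1.77, while those of GFP-low cells stood at 756 and 823 CPM. The ageing difference depended on the libraries chosen: it was -0.074 for 2 years against 7 months, with overlapping counting intervals, and turned to -0.26 for 18 months against 10 weeks and -1.38 for 18 against 7 months. CD41+ cells did not stand apart from 7-month HSCs in Pbx1, with -0.020 and overlapping intervals. The 5 cells of 400000 to 800000 reads at 2 years gave 2.40. The list of Pbx, Meis and Hox genes that holds Pbx1 had medians of 0.63 at 2 years against 10 weeks, 0.34 in GFP-high against GFP-low cells and 0.30 in CD41+ cells against young HSCs, each inside its random range.

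**Figure D1:**
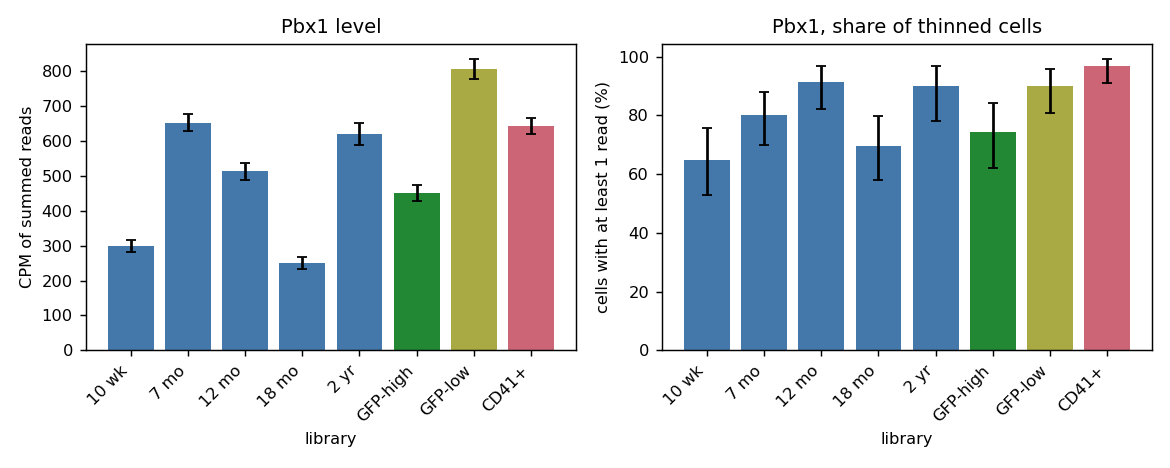
Pbx1 in the 8 libraries, as CPM of reads summed over thinned cells with exact Poisson intervals (left) and as the share of thinned cells with at least 1 read with exact binomial intervals (right). The 10-week and 18-month bars are the lowest, at 299 and 250.3 CPM, and the GFP-low bar is the highest, at 806 CPM.

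The ageing series addressed how HSC transcription differs from 10 weeks to 2 years. In a list of genes that ageing HSCs are known to express more, 23 of 32 expressed members were higher in the 2-year than in the 10-week library, 1 was lower and 8 were neither. The median log2 difference was 1.85 (random lists -0.41 to 0.54). Vwf, the platelet-adhesion glycoprotein that marks platelet-biased HSCs, was at 118 against 17.3 CPM and in 40% against 9.46% of cells. Clu, encoding the chaperone clusterin, was at 193 against 7.03 CPM, and Aldh1a1, a retinaldehyde dehydrogenase, at 270 against 50.3 CPM. Selp, the gene of P-selectin, had 56.4 CPM (47.5 to 66.5) at 2 years and no thinned read at 10 weeks, at least 69.6-fold higher (0 of 74 thinned cells, exact upper limit 4.86%), but it was higher still at 7, 12 and 18 months, at 119.8, 87.7 and 160.3 CPM. Selp and Clu, which was at 120 CPM at 7 months, are among 44 genes nearly absent from the 10-week library but present at each later age. Gstm2 (214 against 25.9 CPM), Mmrn1 (947 against 366 CPM) and Cd9 (304 against 149 CPM) were also higher. Slamf1, the gene of the gate marker CD150, was the member that was lower, at 38.8 against 121 CPM.

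Megakaryocyte and platelet genes were higher too, with 11 of 24 expressed members higher and 0 lower (median 1.499, random lists -0.55 to 0.67). Selp, Vwf, Mmrn1, Cd9, Plek, Itgb3 and Sdpr belong to both this list and the list of HSC ageing. Itgb3, integrin beta-3, was at 115 against 22.4 CPM, its partner Itga2b, the gene of CD41 against which these cells were sorted, at 49.2 against 14.3 CPM, and the platelet glycoprotein gene Gp9 at 74.8 against 23.2 CPM. Mpl, the thrombopoietin receptor, had a log2 difference of -0.16 and Pf4, platelet factor 4, -0.34, neither meeting the rule. All 6 expressed genes of MHC class II antigen presentation were higher (median 1.69, random lists -0.83 to 0.99): H2-Aa was at 104 against 30.8 CPM, H2-Ab1 at 134 against 22.7 CPM and the invariant chain gene Cd74 at 212 against 108 CPM.

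Of the G1/S genes, 10 of 18 were higher and 0 lower at 2 years (median 1.10, random lists -0.46 to 0.56), among them the replicative helicase genes Mcm3 (251 against 109 CPM) and Mcm7 (324 against 137 CPM). G2/M genes had a median of 1.44 (random lists -0.67 to 1.07) with 3 of 21 higher, Kif20b, Tubb4b and Hmgb2, and 1 lower, Cenpe. Ribosomal protein genes were lower by a small amount, with a median of -0.51 over 73 genes (random lists -0.31 to -0.073), and 1 of them met the rule for lower. The myeloid list had the largest median, 3.26 (random lists -0.79 to 1.08), with 7 of 13 members higher and 1 lower. Its high members included the neutrophil granule genes Ltf (286 CPM at 2 years and no thinned read at 10 weeks), Ngp (234 CPM and no thinned read), Camp (111 CPM and no thinned read) and S100a9 (122 against 0.811 CPM). A single well held 79.1% of all reads of S100a8, S100a9, Ngp, Camp and Ltf in the 2-year library, and Ltf and Camp had no read at 7, 12 or 18 months. In cells of at least 200000 reads, without cells rich in these 5 genes, 3 myeloid, 6 G1/S and 22 HSC ageing genes were higher, and 6 MHC class II genes, and the myeloid median was 0.55. Over all cells it was 1.49 with unthinned sums and 1.09 with no filter on low counts, 1.49 with a pseudocount of 10 CPM and 2.17 among genes of at least 50 CPM. The G2/M median was 0.94 among genes of at least 50 CPM and 0.93 with a pseudocount of 10 CPM, and 6 members were higher instead of 3 with a second thinning, with unthinned sums and with the mean of per-cell CPM. The other 16 lists with at least 3 expressed genes had medians from -0.97 to 0.63, inside their random ranges. HSC identity genes were among them, with a median of -0.10, 4 of 36 higher and 4 lower. Nuclear genes of oxidative phosphorylation had a median of -0.27.

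Apart from the myeloid list, most of these list differences lay between 10 weeks and 7 months rather than along the whole series. The mean log2(CPM + 1) of the HSC ageing list was 4.23 at 10 weeks, 5.74 at 7 months, 5.91 at 12 months, 6.24 at 18 months and 6.14 at 2 years, and 26 of 37 members were lowest at 10 weeks. For the megakaryocyte list the means were 4.50, 5.76, 5.98, 5.94 and 6.05. MHC class II genes peaked at 18 months (5.14, 6.19, 6.37, 7.48 and 6.46), and G2/M genes at 7 months (3.44, 6.38, 6.20, 5.69 and 4.92). Against the 7-month library, the 2-year median of the HSC ageing list was 0.47 with 12 members higher, that of the megakaryocyte list 0.16 with 3 higher, that of MHC class II genes 0.18 with 1 of 6 higher, and that of ribosomal proteins -0.23, and the G1/S and G2/M medians were -0.17 and -1.04 with 0 higher in either list. Of these medians, only that of G2/M genes lay outside the random range of the main comparison, on the lower side. Random lists were not drawn against the 7-month library, so the borrowed ranges cannot set these medians apart. For 18 months against 7 months the HSC ageing median was 0.39 with 8 members higher, the megakaryocyte median 0.047 with 0 higher, the MHC class II median 0.93 with 3 higher, the ribosomal median -0.037, the G1/S and G2/M medians -0.26 and -0.63 with 1 and 0 higher, and the myeloid median -0.21 with 0 higher. The 18-month library against the 10-week library gave an HSC ageing median of 1.20, a megakaryocyte median of 0.89 and a myeloid median of -0.41, with 1 myeloid and 6 G2/M genes higher. In cells of 400000 to 800000 reads, of which the 2-year library had only 5, the HSC ageing median was 0.44 with 12 members higher, the megakaryocyte and ribosomal medians 0.97 and -0.30, and the G1/S and G2/M medians were -0.86 and -1.34 with 3 and 5 members higher, and the myeloid median was 1.60 with 4 higher.

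**Figure D2:**
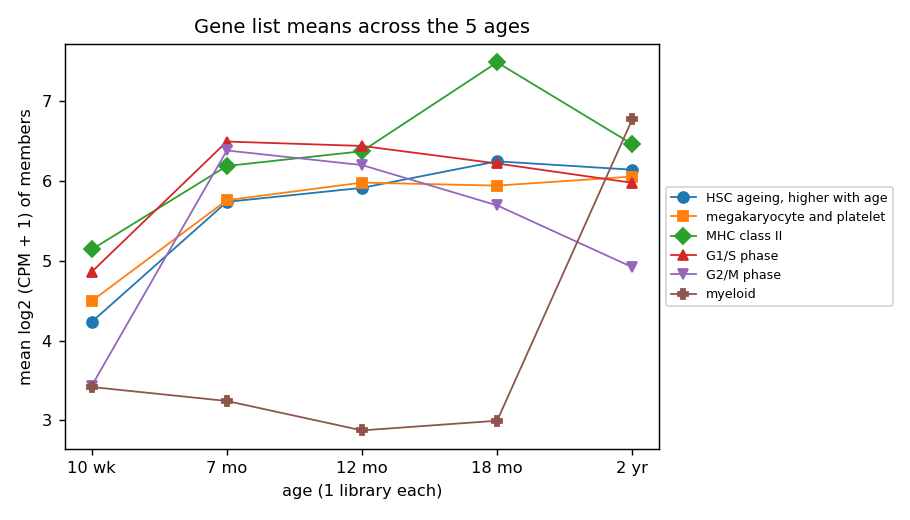
Mean log2(CPM + 1) of the members of 6 gene lists in the HSC libraries of 5 ages, 1 library per age, lines joining the ages only to guide the eye. The HSC ageing list goes from 4.23 at 10 weeks to 5.74 at 7 months and 6.14 at 2 years, and the myeloid list stands apart at 2 years, at 6.77.

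Genes that moved strictly one way across the 5 ages were counted and set against other orders of the libraries. Of 11295 expressed genes, 214 did so and differed at least 2-fold from 10 weeks to 2 years, 116 upward and 98 downward. In an exact two-sided permutation test over the 60 orders of the 5 libraries, 10 orders gave at least as many genes (p = 0.167, smallest possible p = 0.0167), so the order of age was not set apart from other orders. Without the 10-week library p was 0.5, and without the 2-year library 0.25, where the smallest possible was 0.0833. The largest other order gave 311 genes and the median order 135. Of the 10 orders with as many genes, 8 placed the 10-week library next to the 2-year library, as 24 of all 60 orders do; these 2 libraries also had the most reads per cell. None of the 23 gene lists with at least 3 genes had means that moved one way across the 5 ages, where chance gives 0.383.

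**Figure D3:**
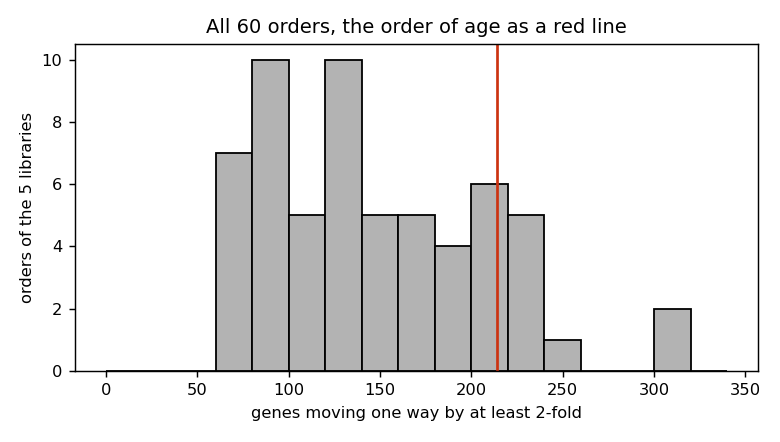
Number of genes moving strictly one way by at least 2-fold for each of the 60 orders of the 5 HSC libraries, as a histogram, with a red line at the order of age. The order of age gave 214 genes and the highest other order 311.

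The named genes of this series are the 12 largest in each direction among these one-way genes that also met the floors on level and share of cells. Upward, Vwf stood at 17.3, 76, 91.4, 101.05 and 118 CPM from 10 weeks to 2 years. Tnfsf10, the gene of the death ligand TRAIL, stood at 40.8, 82.4, 88.9, 91.8 and 279 CPM, Cpt1a, which carries fatty acids into mitochondrial oxidation, at 66.2, 77.9, 131, 190 and 362 CPM, and Gsr, glutathione reductase, at 36.2, 42.1, 44.9, 73.2 and 208 CPM. Slfn9, a Schlafen-family gene, went from 2.43 to 135 CPM. Like Slfn9, Dtd2 (1.08 to 104 CPM), Tab1 (0.811 to 83.2 CPM) and Med14 (4.32 to 97.6 CPM) had under 20 reads each in the summed 10-week library. Asph, Fam195b, Sppl2a and Fbxo30 had log2 differences of 2.75, 2.61, 2.56 and 2.56. Downward, Mdm2, the ubiquitin ligase of p53, stood at 161, 160.5, 124, 73.4 and 24.8 CPM, and Aars, alanyl-tRNA synthetase, at 154, 55.5, 35.1, 30.5 and 11.6 CPM. Gcc2, a golgin, was at 13.2 against 208 CPM and Pogz, a zinc-finger chromatin protein, at 8.4 against 122 CPM at 2 years and 10 weeks. Polr1d, a shared subunit of RNA polymerases I and III, had a log2 difference of -1.45, Rcor1, a corepressor of the CoREST complex, -1.43, and the deubiquitinase gene Usp34 -1.79. Tmem128, Gle1, Aak1, B3gnt2 and Irf2bp2 had differences of -2.02, -1.89, -1.74, -1.41 and -1.41. Flt3, the progenitor receptor tyrosine kinase gene, was not named by the rule and went from 54.3 CPM at 10 weeks to 13.9 CPM at 18 months and no read at 2 years.

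GFP-high and GFP-low cells of the same age and doxycycline time were compared to ask how cells that had kept the label differ from cells that had diluted it. GFP-high cells had more transcripts of HSC identity genes, with 11 of 38 members higher, 2 lower and 25 neither (median 0.53, random lists -0.27 to 0.23). Procr, the endothelial protein C receptor, was at 144 against 13.0 CPM and in 42.4% against 5.63% of cells. Ly6a, the gene of the gate marker Sca-1 (chromosome 15, 74994877 to 74998031), was at 175 against 21.4 CPM and in 59.1% against 9.86% of cells. The HSC transcription factor genes Hlf (607 against 235 CPM), Mecom (328 against 116 CPM) and Gata3 (221 against 60 CPM) were higher, and Slamf1 (55.8 against 161 CPM) and Ctnnal1 (22.1 against 92.1 CPM) were lower. MHC class II genes differed most, with 5 of 6 higher (median 2.50, random lists -0.73 to 0.69): Cd74 was at 441 against 20 CPM and in 71.2% against 2.82% of cells, and H2-Aa at 462 against 47.9 CPM.

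G1/S genes were lower in GFP-high cells, with 10 of 20 lower and 0 higher (median -1.49, random lists -0.44 to 0.41). Mcm6 was at 111 against 491 CPM, Mcm5 at 81.2 against 297 CPM and Uhrf1, needed to maintain DNA methylation at replication, at 42.1 against 241 CPM. G2/M genes did not follow: their median was 0.90 on the higher side, with 2 of 24 higher, Cenpf and Tubb4b, and 1 lower, Cks2, and it was -1.04 in cells of 400000 to 800000 reads. Leaving out cells rich in G2/M reads, which chooses cells by the genes measured, turned it too. Mki67 was at 185 against 209 CPM. Nuclear genes of oxidative phosphorylation were lower, with 15 of 43 lower and 0 higher (median -0.51, random lists -0.27 to 0.20), such as Cox6b1 (100.91 against 261 CPM) and Ndufs2 (50.9 against 181 CPM). Interferon response genes were higher in 7 of 24 cases and lower in 2 (median 0.53, random lists -0.40 to 0.39; 11 higher with unthinned sums, and 13 with a median of 0.90 with the mean of per-cell CPM), with Rsad2, Iigp1 (183 against 30.4 CPM) and Irgm1 (283 against 55.5 CPM) higher and Ifit2 (1.82 against 64.5 CPM) and Ifi27l1 lower. Immediate early genes were higher in 8 of 21 cases and lower in 1 (median 0.37, random lists -0.28 to 0.25), with Fos at 1426 against 766 CPM, Klf2 at 163 against 71.3 CPM and the heat-shock gene Hspa1a lower at 16.4 against 128 CPM. Megakaryocyte and platelet genes had a median of -0.0072, but 8 of 22 were lower and 3 higher. Among them Itga2b was at 75.2 against 146 CPM, Pf4 at 18.8 against 86.8 CPM and Gata1 at no thinned read against 45.9 CPM. For Gata1 this was 50.5-fold against a floor of 3 counts, and the exact limit of its log2 difference nearest to no change was -5.34. Reads of Gata1 were held by 7.25% of unthinned GFP-high cells, against 23.8% of GFP-low cells. Itga2b in GFP-low cells was at 32.2 CPM in run 1 and 184 CPM in run 2, so its direction in CPM held in run 2 only. GFP-high and GFP-low cells were not sorted on CD41. Ribosomal protein genes (-0.17) and 4 genes of the X and Y chromosome list (0.79, random lists -0.74 to 0.78) also lay just outside their random ranges. The HSC ageing list lay inside, with a median of 0.20, 7 of 37 higher and 7 lower.

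The named genes higher in GFP-high cells were, besides Cd74, Procr, H2-Aa and Ly6a, the copper transporter gene Atp7a (105 against 9.86 CPM), the phosphatase gene Ptpn14 (143 against 14.4 CPM), G6pdx, the first enzyme of the pentose phosphate pathway (186 against 21.7 CPM), Abcg3 (219 against 27.0 CPM), the proteoglycan gene Bgn (328 against 43.1 CPM), the interferon-induced ribonuclease gene Rnasel (272 against 38.6 CPM), H2-Eb1 (139 against 20.6 CPM) and the focal-adhesion gene Tns1 (198 against 32.4 CPM). Those lower were led by Smim13, at 1.82 against 250.1 CPM. They included the DNA ligase gene Lig1 (30.3 against 188 CPM), Tipin (32.4 against 238 CPM), the mitochondrial serine hydroxymethyltransferase gene Shmt2 (22.1 against 238 CPM), Wdr75 (10.9 against 124 CPM) and Rpf1 (13.3 against 107 CPM). Nkg7, a granule membrane gene, was at 9.09 against 106 CPM, Ythdf1, a reader of methylated RNA, at 9.09 against 114 CPM, and the calcium pump gene Atp2a2 at 21.2 against 138 CPM. D10Wsu102e, Ube3c and Dnaaf2 had log2 differences of -3.76, -2.80 and -2.77. Not every list difference was larger than that between the runs of GFP-low cells: the run 1 minus run 2 median was -0.59 for HSC identity, -1.15 for immediate early, 0.90 for G2/M, -0.90 for X and Y chromosome and -0.25 for ribosomal protein genes, against -0.47 for interferon, -0.17 for MHC class II, 0.42 for G1/S and -0.20 for oxidative phosphorylation genes. With run 1 alone as GFP-low cells the HSC identity median was 1.09, that of immediate early genes 1.26, of interferon genes 0.84, of G2/M genes 0.21 and of ribosomal proteins 0.015. With run 2 alone the immediate early median was 0.19 and that of G2/M genes 1.35. Unthinned sums left 9 oxidative phosphorylation genes lower and gave a ribosomal median of -0.11, cells of 400000 to 800000 reads a ribosomal median of -0.082, no filter an immediate early median of 0.57, and genes of at least 50 CPM gave a G2/M median of 0.13 and an interferon median of 0.86.

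CD41+ LSK cells were compared with CD41- HSCs of the same age of 10 weeks; the sort also differed in CD34. CD41+ cells had more transcripts of cell-cycle genes than the 10-week library. All 24 G2/M genes were higher (median 3.07, random lists -0.43 to 0.88), as were 18 of 23 G1/S genes with 0 lower (median 2.28, random lists -0.45 to 0.66). Mki67 was at 489.6 against 83.0 CPM and in 63.5% against 24.3% of cells, Top2a, the replication-linked topoisomerase, at 592 against 64.3 CPM and Mcm3 at 529.8 against 109 CPM. Megakaryocyte and platelet genes were higher in 17 of 24 cases and lower in 0 (median 1.84, random lists -0.44 to 0.75). Itga2b, the gene of CD41 itself (chromosome 11, 102453297 to 102469883), was at 312 against 14.3 CPM, Pf4 at 307 against 57.8 CPM, Vwf at 126 against 17.3 CPM and the megakaryocyte-erythroid transcription factor gene Gata1 at 161 against 1.89 CPM and in 38.5% against 2.7% of cells.

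Glycolysis genes were higher in 9 of 16 cases, such as Pgk1 (491 against 191 CPM) and Pkm (569 against 286 CPM), and lower in 1, the hexokinase gene Hk2 (95.6 against 321 CPM; median 0.76, random lists -0.54 to 0.44). Of Polycomb and DNA methylation genes 8 of 19 were higher, including Ezh2 (278 against 60.3 CPM) and Dnmt1 (337 against 76.5 CPM), and 3 lower, Sirt1, Tet2 and Kdm6b (81.2 against 296 CPM; median 0.73). Immediate early genes were higher in 12 of 20 cases and lower in 1 (median 0.73, random lists -0.51 to 0.42), with Fos at 1183 against 204 CPM and Dusp1 at 447 against 81.9 CPM. Lists on the lower side were those of NF-kB and TNF response (median -1.29; Rel 30.2 against 177 CPM, with 1 of 11 higher and 2 lower), p53 targets (-0.71; Cdkn1a 58.3 against 162 CPM, with 1 of 12 higher and 3 lower), lymphoid and multipotent progenitor genes (-0.78; Flt3 1.88 against 54.3 CPM, with 3 of 11 higher and 1 lower), autophagy and lysosome (-0.48, 7 of 21 higher and 5 lower) and ribosomal proteins (-0.44, 0 of 74 higher or lower), the last 2 just outside their random ranges. The p53 median was 0.10 with no filter on low counts but -1.58 among genes of at least 50 CPM, -1.41 without cells rich in G2/M reads, -1.25 with run 2 alone and -1.06 without the top cell of each gene. With unthinned sums or the mean of per-cell CPM 6 p53 targets were lower, 5 with thinning to 200000 reads, and 0 lymphoid genes were higher. The lymphoid median was 0.072 among genes of at least 50 CPM. HSC identity genes had a median of -0.37 with 2 of 34 higher and 7 lower, inside the random range, with Ly6a at 44.2 against 278 CPM and Hlf at 199 against 747 CPM among those lower. Procr, at 11.04 against 67.8 CPM, was in too few cells of either library to meet the rule. With run 1 of CD41+ cells alone the glycolysis median was 0.38, the Polycomb median 0.46, the NF-kB median -0.59, the lymphoid median -1.21 and the ribosomal median -0.77, with 5 glycolysis genes higher, and unthinned sums and the mean of per-cell CPM left 3 glycolysis genes higher. The lymphoid median was -0.51 without the top cell of each gene and -0.14 with no filter, and the autophagy median -0.74 with run 1 alone, -0.31 with run 2 alone and -0.30 with no filter; a second thinning left 2 autophagy genes lower. The NF-kB median was -0.80 with a pseudocount of 10 CPM and -0.82 among genes of at least 50 CPM. In cells of 400000 to 800000 reads the autophagy and NF-kB medians were -0.18 and -0.54. The myeloid median was 1.54, inside its random range, with Ngp at 273 CPM in run 1 and 1.62 CPM in run 2 of CD41+ cells.

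Of the 12 named genes higher in CD41+ cells, Kif20b, Ccnb1, Aurkb and Ube2c belong to the G2/M list. Kif20b (chromosome 19, 34922335 to 34975750), a mitotic kinesin, was at 151 CPM and in 45.8% of cells. It had no read in thinned young HSCs and was 186-fold over a floor of 3 counts there. Other genes with no read in thinned young HSCs were set against the same floor. Cyclin B1 (Ccnb1) was 179-fold, Aurora kinase B (Aurkb) 158-fold and the recombination gene Rad54l 140.5-fold over it. Ube2c of the anaphase-promoting machinery was 129.8-fold, the kinetochore gene Casc5 124-fold, Tsnax 103-fold and the DNA glycosylase gene Neil3 86.8-fold over it. Lower exact limits of these log2 differences ran from 7.24 for Kif20b to 6.13 for Neil3, so the folds over the floor are not lower limits. Prc1, a spindle midzone gene, was at 259 against 2.7 CPM, Ckap2l at 228 against 1.62 CPM, Gpn1 at 115 against 0.811 CPM and Ino80c at 99.4 against 0.27 CPM. Some of these genes were not so low in HSCs of other ages. Kif20b was at 84.7 CPM at 7 months and 155 CPM at 12 months. Ccnb1 was at 93.6 CPM, Tsnax at 82.4 CPM and Gpn1 at 136 CPM at 7 months. Tsnax reached 138 CPM at 18 months. Others were low in run 2 of GFP-low cells, with Ube2c and Ckap2l at 0 CPM, Aurkb at 2.26 CPM and Prc1 at 3.77 CPM. In run 1 of GFP-low cells these 4 were at 28.9, 90, 38.9 and 70 CPM. Casc5 was at 3.33 and 11.3 CPM in runs 1 and 2 of GFP-low cells, and Ino80c at 4.44 and 60.4 CPM. Neil3 was at 93.3 and 10.2 CPM there, and Rad54l at 61.1 and 56.2 CPM. Kif20b, Tsnax and Gpn1 are among the 44 genes nearly absent from the 10-week library, so their folds rest in part on low values there. Whether these low values come from age or from the library cannot be told apart. Unthinned young HSCs held reads of Ube2c in 24.1% and of Kif20b in 1.27% of cells. The named genes lower in CD41+ cells included Ly6a, the T-cell and HSC transcription factor gene Gata3 (22.9 against 145 CPM), the Wnt pathway genes Tcf7l2 (80.8 against 555 CPM) and Lgr4 (26.9 against 187 CPM), and the AP-1 gene Fosl2 (25.8 against 190.3 CPM). Trim36 (2.5 against 55.1 CPM), Usp53 (14.0 against 126 CPM), Fam193b (10.6 against 94.3 CPM), Sult1a1 (11.04 against 90 CPM), Glg1 (17.1 against 133 CPM), Slc38a6 (7.5 against 57.6 CPM) and Mical3 (10.8 against 75.1 CPM) were lower as well. All 24 named genes kept their direction in both runs, but sizes differed. The genes were chosen from the sum of these runs, and both runs were set against the same young HSCs. Their shared direction is therefore not independent support. Log2 differences in runs 1 and 2 were -1.06 and -4.08 for Mical3, -1.68 and -3.39 for Slc38a6 and -5.91 and -2.29 for Ly6a. The run 1 minus run 2 medians were 0.41 for G2/M, -0.081 for G1/S and 1.09 for megakaryocyte genes. The median of all expressed genes was 0.17 on the log2 scale in this comparison, and median-of-ratios scaling moved every gene by -0.15.

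Much of this comparison depended on the 10-week library. Set against the 7-month HSCs instead, an alternative added after the data were seen in which age differs too, CD41+ cells had a G2/M median of 0.74 and a G1/S median of 0.86, with 16 members of each list higher, and a megakaryocyte median of 0.74 with 11 members higher. Of these medians, those of G2/M and megakaryocyte genes lay inside the random ranges of the main comparison and that of G1/S genes outside. Random lists were not drawn for the comparison with 7-month HSCs, so the borrowed ranges cannot set its medians apart. The glycolysis median was then 0.040 with 0 members higher, the Polycomb median 0.078 with 5 higher and 1 lower, the NF-kB median -0.65, the p53 median -0.11 and the ribosomal median -0.13. No lymphoid gene was then higher, no p53 target lower and no autophagy gene higher or lower. Pbx1 had a log2 difference of -0.020 and Gpn1 of -0.24, the first within counting error of 0. Among the named genes, Kif20b was at 0.83, Ccnb1 at 0.63, Tsnax at 0.017, Ly6a at -2.65 and Fosl2 at -2.73 on the log2 scale.

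**Figure D4:**
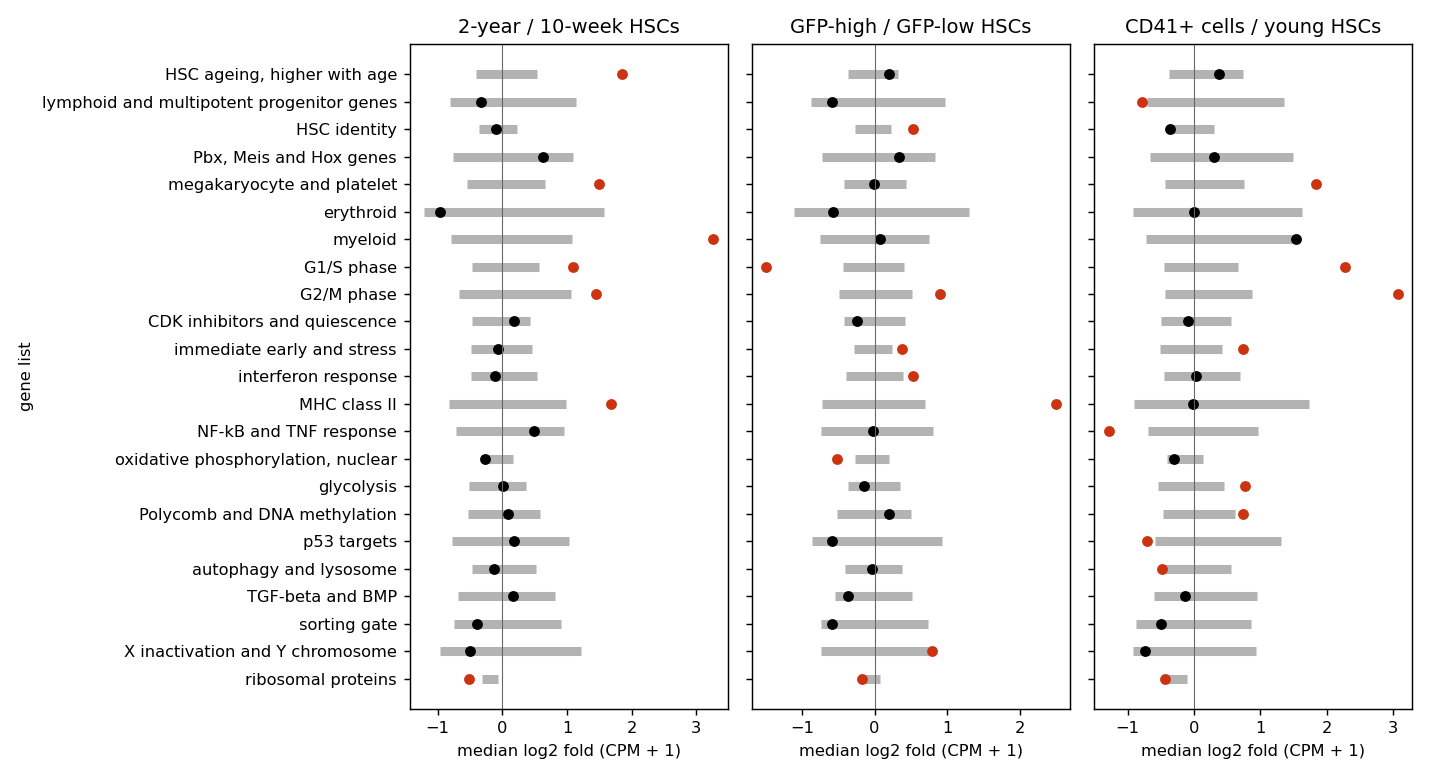
Median log2 difference of each gene list (points) in the 3 comparisons, with the central 95% of medians of 10000 expression-matched random lists as grey bars; red points lie outside the bar. G2/M genes in CD41+ cells (3.07), MHC class II genes in GFP-high cells (2.50) and HSC ageing genes at 2 years (1.85) lie far to the right of their bars.

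Markers of other cell types differed by library. Neutrophil granule genes were found at 2 years (Ltf 286, Ngp 234 and S100a9 122 CPM) and in CD41+ cells (S100a9 66.9 and Ngp 63.8 CPM). Nkg7, of the T and NK cell list, was at 208 CPM in CD41+ cells, 97.8 CPM at 10 weeks and 9.09 CPM in GFP-high cells. The haemoglobin gene Hba-a1 had no read in any library and Cd79a of B cells none after thinning, and Cd19, Csf1r of monocytes and Gzmb of cytotoxic cells stayed at or below 2.92 CPM. Cxcl12, a stromal chemokine gene, was at 24.3 CPM at 12 months, in 2 of 70 thinned cells, and at 43.8 CPM in CD41+ cells. In CD41+ cells it was at 0 CPM in run 1 and 56.8 CPM in run 2. The erythroid transcription factor gene Klf1 was at 12.5 CPM at 7 months, and the beta-globin entry Beta-s at 58.8 CPM there. Mpo, a granulocyte progenitor gene, was at 7.71 CPM in CD41+ cells and under 1 CPM elsewhere. Cpa3, a mast-cell gene that HSCs also express, was at 29.7, 12.7, 27.7, 25 and 26.8 CPM from 10 weeks to 2 years. It was at 2.42 CPM in GFP-high cells and had no thinned read in GFP-low cells. The lists of B cell, T and NK cell, stromal and endothelial, and mast cell and basophil genes had at most 2 expressed members in each comparison and were given no median. Cd48, the gene of a marker the sort excluded, was at 7.29 CPM at 7 months and 7.08 CPM in CD41+ cells and had no read in the other 6 libraries.

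Fold changes were set side by side across genes, which are not independent replicates, to ask whether GFP dilution or CD41 expression goes with the ageing difference. The GFP-low over GFP-high and 2-year over 10-week folds shared no library and had Pearson's r = 0.0152 and Spearman's rho = 0.0128 over 10933 genes. The CD41+ over young HSC folds against the 2-year over 7-month folds gave r = -0.127 and rho = -0.14 over 10931 genes, again with no shared library. With the 10-week library in both comparisons, CD41+ over young HSC and 2-year over 10-week folds gave r = 0.567 and rho = 0.549. Groups without any effect were simulated by drawing all of them, the shared control included, from cells of the 7-month library. Features particular to the 10-week library are therefore not in the simulated values. These groups gave r = 0.467, and the covariance was 1.87 against 0.695 simulated, a difference of 1.17. The control could not be split, since it is 1 library, so part of this excess may come from the 10-week library itself. GFP-low over GFP-high and CD41+ over young HSC folds gave r = 0.0403 and rho = 0.0443 over 10836 genes, a pair added after the data were seen.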

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

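Tests chosen after the result was seen were those on cells of at least 200000 or of 400000 to 800000 reads, on a second or deeper thinning, on single runs, on 18 against 7 months, on CD41+ cells against 7-month HSCs, on the order of ages without 1 library, and on the agreement of the GFP and CD41 comparisons. Over all alternatives, 2326 values stayed within a tolerance, 513 moved beyond it and 20 were labelled as changed in sign. Some of these 20 went to values near 0. The tolerance was a counting interval, a count range or, for list medians, a width based on the random range. Medians inside their random range were not given the sign label, so the 20 undercount sign changes. In ageing the p53 median kept its sign in 9 of 17 alternatives and the HSC identity median in 12 of 17. The autophagy median of the GFP comparison kept it in 7 of 16, and the ageing median of oxidative phosphorylation in all 17. The cause of these changes was not tested except where an alternative changed the libraries or cells compared. No paired analysis was possible because each group has 1 library. Leaving mitochondrially encoded genes out was not run, since the table holds none. Unthinned sums gave an HSC ageing median of 2.34, a Pbx1 ageing difference of 0.92 and 17 HSC identity members higher in GFP-high cells. Pbx1 in CD41+ cells was 0.99 with TMM, 0.95 with median-of-ratios, 1.28 without the top cell, 0.99 without G2/M-high cells, and 1.77 and 0.82 with run 1 and run 2 alone. Without G2/M-high cells the G2/M median in GFP-high cells was -1.04. Cells of 400000 to 800000 reads, only 5 of them at 2 years, gave an HSC ageing median of 0.44 with 12 members higher, G1/S -0.86, G2/M -1.34, Pbx1 2.40, Med14 -1.31 and Gsr -0.54 in ageing, and G2/M -1.04 and Pbx1 -0.65 in the GFP comparison. GFP-low run 1 alone gave an HSC identity median of 1.09 and a ribosomal median of 0.015. With 7 months as young, HSC ageing was 0.47 with 12 members higher, G1/S -0.17, G2/M -1.04 and Pbx1 -0.074. With 18 months as old, HSC ageing was 1.20, myeloid -0.41 and Pbx1 -0.26. For 18 against 7 months, HSC ageing was 0.39 with 8 members higher, myeloid -0.21, G1/S -0.26, G2/M -0.63 and Pbx1 -1.38. CD41+ cells against 7-month HSCs had a megakaryocyte median of 0.74 with 11 members higher, Pbx1 -0.020 and Gpn1 -0.24. With no filter the p53 median in CD41+ cells was 0.10. At 50 CPM the HSC ageing median was 1.37 and the lymphoid median in CD41+ cells 0.072. Cells with at least 5 reads of Pbx1 made up 32.4, 61.2, 64.3, 44.7, 64% of cells from 10 weeks to 2 years, 54.5% of GFP-high, 81.7% of GFP-low and 88.5% of CD41+ cells, and in the same order unthinned shares were 96.2, 98.8, 100, 84.8, 100%, 95.7%, 93.8% and 100%. Depth limits shares: a gene absent from thinned cells can be present in unthinned ones.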

Other observations

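Except for the tests of GC content or transcript length and the first test of cycling cells, the tests in this part were chosen after the result was seen.

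Reads of S100a8, S100a9, Ngp, Camp and Ltf in the 2-year library came mostly from 1 well, with 9053 reads or 79.1% of the total. An even spread of expression over the 2-year cells is therefore argued against. Low expression in other wells cannot be excluded this way, since 1 high well would hold most reads in either case. Of the other 52 wells, 13 held 112 to 177 reads of these genes and 39 held 3 to 27. The median of deep wells was 0.12 times that of shallow wells, 15 against 125 reads. This meets the prediction for reads of 1 well being assigned to others, which asked only that reads not rise with depth. A fall with depth was not predicted, so other sources of reads in shallow wells stay open. In wells of 500000 to 700000 reads, 1 to 10 reads were found in 44.0% of gene and well pairs at 10 weeks, 2.0 times the share at 12 months (22.0%), which depth of the wells does not account for. The 2-year library had 42.4% from 2 wells. Unthinned shares of cells in these 2 libraries may therefore be too high. Thinned shares may be too high as well: S100a9 was in 38%, Ngp in 36% and Ltf in 26% of thinned 2-year cells. Calls of list members and named genes that use shares of these 2 libraries carry the same limit. No biological explanation was tested.

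There were 44 genes nearly absent from the 10-week library (median 2.7% of thinned cells) but present at each later age (18.8, 20, 17.1 and 17%). Lower depth is argued against, since the 10-week wells had 1.26 times the median reads of the 7-month wells. Of 2 properties looked at, the median GC content lay at percentile 93.8 of matched sets and the median longest transcript, 2766 bases, at percentile 2.03, so shorter transcripts may have a part in it. The first test of cycling cells decided nothing, as 50% of the genes (22 of 44) stayed above 12% of cells at every later age without cycling cells; a second test, chosen after that outcome, found a lowest median share of 15.9%, which argues against cycling cells as the whole source and leaves a part open. CD41+ cells of 10 weeks held the genes in a median 26.0% of cells, but they are another population, so age cannot be told apart from an effect of the 10-week library.

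Ly6a, Procr and MHC class II genes were low in GFP-low cells. As the whole cause, CD41+ cells like those of the 10-week library are argued against by Itga2b. A share large enough for Procr (98.6%) would put Itga2b at 309 CPM, where 146 CPM was measured, at 32.2 and 184 CPM in runs 1 and 2. Ly6a does not decide this. Summed over runs it was at 21.4 CPM (16.9 to 26.8) in GFP-low cells, below 44.2 CPM (38.4 to 50.5) in CD41+ cells. In runs 1 and 2 it was at 37.8 and 15.8 CPM in GFP-low cells and 3.64 and 56.2 CPM in CD41+ cells, so the order depends on the run. CD41+ cells of the older mice were not measured and stay open. Shallow wells are argued against by an MHC class II median of 2.55 in cells of at least 200000 reads. More dividing cells among GFP-low cells may explain the G1/S genes but cannot be told apart from other causes, because the G2/M median was 0.90 on the other side but -1.04 in cells of 400000 to 800000 reads. An effect of the library, with 1 per group, and the division history of the cells stay open, untested.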
